A study of Mus musculus with 34 samples.

How the data were processed

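The data were bulk RNA sequencing of mouse skin (Illumina, RNA extracted with Trizol, per the labels' protocols), with 18 samples of back skin and 16 of footpad skin in 17 groups of 2. The deposited values were FPKM from the authors, in 2 tables, 1 per tissue, with 47633 genes each and 1 mean column per group. TopHat2 2.1.0, Cufflinks 2.2.1 and the mouse genome build mm10 are named per the submitters' processing notes. Neither the annotation release, nor the strand setting, nor how the samples of a group were averaged is recorded there. Gene symbols were used as the tables give them. Positions, gene types and exon lengths came from GENCODE release M21 (GRCm38, the same assembly as mm10), which holds 47217 of the 47633 identifiers, 45069 of them with the same symbol. Symbols standing on several lines, 116 in number, were left out.

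Groups, comparisons, gene lists, the rule for naming genes and the first 3 alternatives were set before the data were examined. The planned analysis was a limma fit on log2 FPKM of single samples with a camera test of lists. As the tables hold only means per group, this could not be fitted, and the fallback written beforehand was used. For each gene the log2 ratio of (mean FPKM + 1) was taken between groups, with no test, SD or adjusted value. This scale understates changes of genes with low FPKM. The planned filter of 1 FPKM in 2 samples became 1 FPKM in at least 1 mean column of the tissue. An interaction is the difference of 2 such log2 ratios, so it carries more noise than a single ratio. A gene was counted as higher or lower at 2-fold or more.

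The 23 comparisons were irradiated against unirradiated skin of the same genotype and tissue, 24 h against 6 h in wild-type back skin, each knockout against wild type before irradiation, and each knockout response minus the wild-type response. The 39 gene lists were written from general knowledge of skin, hair, immune and radiation biology. A list with at least 5 measured members was described by its median log2 ratio, placed among 10000 random lists of the same size matched on mean expression in 20 bins, and called outside their range below percentile 2.5 or above 97.5. Random lists do not take into account that members of a list can vary together between skin pieces, so the unirradiated genotype differences are given as a scale.

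Named genes were Krt17 and Trp53 in every group, then per comparison the 8 genes with the largest increase and the 8 with the largest decrease (5 and 5 for genotype and interaction comparisons) among those with 5 FPKM or more in at least 1 group, and the 4 members of each list with the largest changes. Gene models named only by a number were left out. Of the genes that met this rule, those printed and those drawn were picked after their values were seen. A gene listed at 0 in a column, with a median of 5 FPKM or more over the other columns, was treated as missing in that column, since abundant genes such as Krt10 were also listed at 0. This concerned 32 values in the footpad and 19 in back skin.

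The overlap of 2 lists of changed genes was set beside that of independent lists, the product of their sizes over the number of genes compared. Overlaps were taken only between comparisons with separate control groups. The alternatives were a pseudocount of 0.1 FPKM, no filter, and rescaling of columns by their median ratio to the geometric mean column. A filter of 5 FPKM, listed zeros kept as 0, and leaving out genes at least 8-fold from all other columns in 1 column were added after seeing the data.

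The counting and the placing of lists were tested on simulated data with an assumed log2 SD of 0.25 per sample. In a simulation of wild-type back skin at 6 h, 100% of genes raised 4-fold and 60.6% of those raised 2-fold passed the 2-fold threshold, as did 0% of 13580 unchanged genes. In a simulation of wild-type footpad at T3, 48.5% of genes raised 2-fold passed. Genes lowered 2-fold passed less often, 35.3% of them in the back skin simulation and 32.4% in the footpad one. The real spread between samples is not known. The 0% follows from the small assumed spread, which was the same for each gene, so it gives no rate of false calls in these data. FPKM totals per column lay between 854202 and 1095024, and the number of reads behind a value is not recorded, so no interval or detection limit could be given. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.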

Results

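RNA was sequenced from skin of mice aged 8 to 10 weeks, before and after ionizing radiation. Back skin with hair in its growth phase (18 samples) came from wild-type mice, mice without the keratin gene Krt17 and mice without the tumour suppressor p53, as unirradiated controls (0 h) and at 6 h and 24 h after 5 Gy. Footpad skin (16 samples) came from wild-type and Krt17 knockout mice, as controls (T0) and at points named T3, T6 and T9 after 40 Gy, for which the labels give no unit of time. Each of the 17 groups held 2 samples, and the values used are the authors' mean FPKM (fragments counted per transcript length and per mapped fragments) of each group. The values of single samples, their spread and the number of reads were not given, so no difference has a replicate check and all are given as sizes only, as log2 ratios of FPKM + 1. The columns summed to between 854202 and 1095024 FPKM.

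Krt17 encodes a stress-inducible keratin that is also made in growing hair follicles. In wild-type back skin it stood at 1650.3, 1358 and 1919 FPKM at 0, 6 and 24 h, in p53 knockout skin at 1475, 883 and 1396, and in Krt17 knockout skin at 18.9, 14.7 and 29.9. In wild-type footpad it stood at 124, 92.6, 183 and 835 FPKM at T0, T3, T6 and T9, and in Krt17 knockout footpad at 18.2, 26.2, 68.1 and 58.8. The gene lies on chromosome 11 from 100256217 to 100261029 on the minus strand (GRCm38). Krt17 was thus lowest in the groups that carry the Krt17 knockout label in both tissues, although it was not at 0 there, and its sequence is close to that of other type I keratins.

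Trp53, which encodes p53 (chromosome 11, 69580359 to 69591873, plus strand), was still measured in p53 knockout back skin, at 25.8, 18 and 28.8 FPKM. Wild-type back skin had 43.8, 19.3 and 21.5 FPKM of Trp53, and Krt17 knockout back skin had 30.1, 28.6 and 20.9. In the footpad, Trp53 lay at 20.2, 20.9, 22.8 and 25.5 in wild type and at 21.2, 20.9, 19.7 and 24.1 in the Krt17 knockout. A value for the whole gene cannot check a deletion of part of it, so Trp53 neither bears out nor contradicts the p53 knockout label.

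Irradiation of wild-type back skin addressed what 5 Gy changed in skin with growing hair. Genes that p53 switches on were higher at 6 h, among them Bbc3 and Pmaip1, which promote cell death, and Fas, a death receptor. Genes of mitosis were lower at 6 h and lower still at 24 h. Interferon-induced genes were lower at 6 h. By 24 h, signals of the hair matrix, the dividing base of the follicle, were lower, while genes for the keratin-associated proteins that fill the hair shaft were higher.

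The p53 target list (38 genes) had a median log2 ratio of 0.52 at 6 h, with 31 members higher, and of 0.38 at 24 h, above all 10000 matched random lists at both times. Bbc3 went from 5.00 to 20.7 FPKM at 6 h and stood at 9.29 at 24 h. Ccng1, a p53-induced cyclin, stood at 15.2, 39.8 and 33.3 FPKM. Mgmt, which repairs alkylated guanine, was 3.50 FPKM at 6 h but 28.4 at 24 h, against 4.33 in controls. The mitotic list (30 genes) had medians of -1.03 and -1.15, both below all 10000 random lists, and 26 of its members were at least 2-fold lower at 24 h. Mki67, a marker of dividing cells, stood at 17.4, 6.57 and 2.93 FPKM. DNA replication genes had medians of -0.40 and -0.90, and DNA repair genes of -0.28 and -0.83.

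Shh, a growth signal of the hair matrix, went from 5.90 to 4.63 FPKM at 6 h and 1.20 at 24 h. Msx1, a matrix transcription factor, had log2 ratios of -0.72 and -2.16, and the Hedgehog list (8 genes) had medians of -0.40 and -0.99. The keratin-associated list (42 genes) had a median of 1.07 at 24 h with every member higher, led by Krtap19-4 at a log2 ratio of 1.80, whereas its median of -0.14 at 6 h turned to 0.03 when the columns were rescaled to a common median. All genes with a Krtap symbol, a set wider than this list, made up 13.1% of the FPKM total in controls and 25.1% at 24 h. The interferon list (36 genes) had a median of -1.31 at 6 h, with Ifit3, an antiviral gene, at 15.5 FPKM before and 1.45 after, and of -0.44 at 24 h.

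Of the described genes in wild type, Pdk4, a kinase that restrains glucose oxidation, had the largest log2 ratio at 6 h (3.25 to 98.0 FPKM), with Trim63, a ubiquitin ligase of muscle, at a log2 ratio of 3.72, Zbtb16, a transcription factor, at 2.59 and Txnip, an inhibitor of thioredoxin, at 2.59. Dbp, an output gene of the daily clock, was lower at 6 h (7.56 to 2.52 FPKM). At 24 h the leading genes included Lcn2, an iron-binding antibacterial protein (3.26 to 148 FPKM), and Saa3, an acute-phase protein (8.79 to 295). Collagen genes were lower at 24 h, with Col1a1 at -2.37 and a median of -0.85 over 23 fibroblast and matrix genes, measured from a wild-type control that was the highest of the 3 control groups for this list. The skeletal muscle list stood at 1.16 and 0.71, and as it was also 1.01 in unirradiated Krt17 knockout skin against wild type and 0.61 in the p53 knockout, the wild-type controls had the lowest muscle values of the 3 control groups. Foxn3, Ece1, Mrm1, Cacnb4, Snhg9 and Lars2 also met the size rule, but moved irregularly from column to column. Lars2, for example, stood at 62.1, 1039 and 84.8 FPKM.

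In wild type, 267 genes were at least 2-fold higher and 482 lower at 6 h among 15018 compared, and 322 were higher and 520 lower at 24 h. Both times are set against the same wild-type control column, so the excess of lower genes does not count as 2 separate observations. The interactions in back skin use that column as well. The median of all genes was -0.15 and -0.20, and after rescaling no excess of lower genes was left, with 358 higher and 313 lower at 6 h and 474 and 282 at 24 h. The higher share thus went from 35.6% to 53.4% at 6 h and from 38.2% to 62.7% at 24 h. Rescaling brings the typical ratio close to 0 by construction, so it cannot show whether the excess of lower genes was real. With a pseudocount of 0.1 FPKM the excess was larger, with 532 higher and 1262 lower at 6 h and 530 and 1261 at 24 h.

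**Figure D1:**
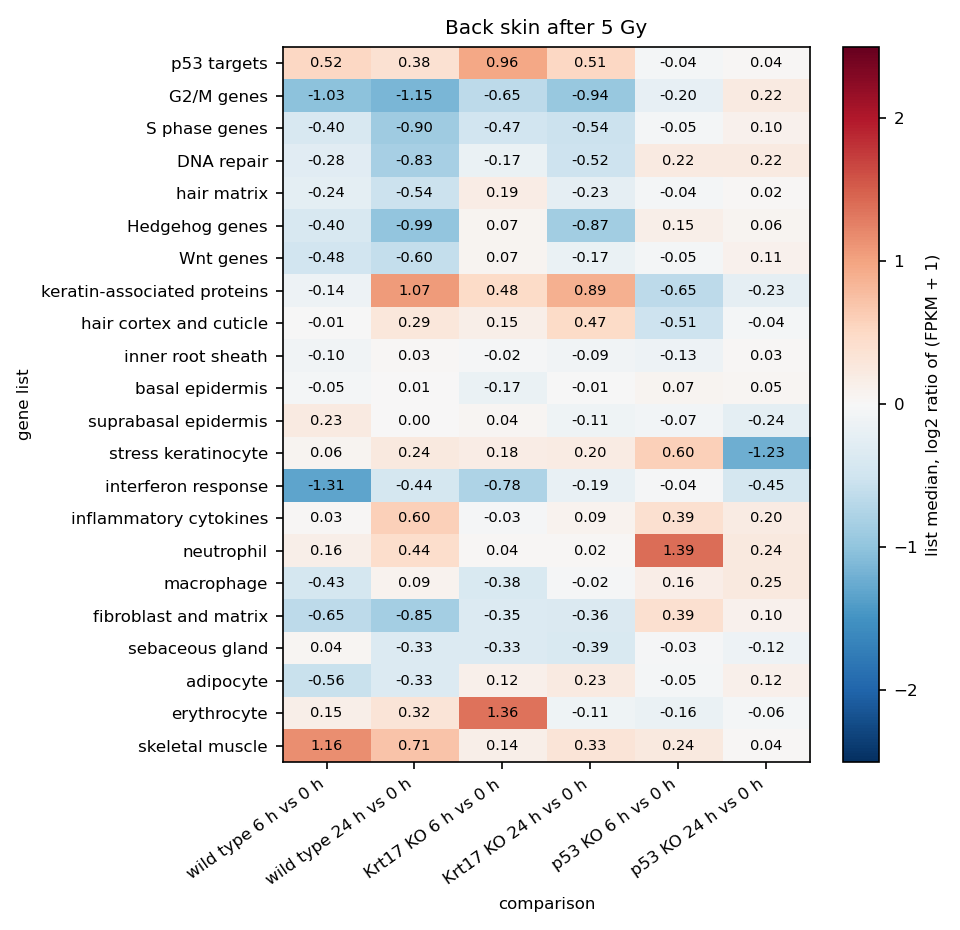
Median log2 ratio of FPKM + 1 over each gene list in irradiated back skin against the same genotype at 0 h, with 1 mean column per group. Mitotic genes lay at -1.15 in wild type, -0.94 in the Krt17 knockout and 0.22 in the p53 knockout at 24 h, and the keratin-associated median in wild type at 6 h changed sign from -0.14 to 0.03 under rescaling.

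Between 6 h and 24 h in wild type, the question was which early changes lasted. Among the largest single genes, Saa3 had a log2 ratio of 5.60 at 24 h against 6 h and Lcn2 of 3.56. Rrad, which encodes a small GTPase, stood at 4.88, and G0s2, an inhibitor of fat breakdown, at 3.67 after a low point of 1.70 FPKM at 6 h. Txnip (-2.87) and Ucp3 (-2.79), a mitochondrial carrier of muscle, were lower again. The keratin-associated list stood at 1.38, the interferon list at 0.86 and the mitotic list at -0.25. In all, 450 genes were at least 2-fold higher and 370 lower at 24 h than at 6 h.

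The Krt17 knockout response showed what 5 Gy changed in back skin without this keratin. The p53 targets were higher here too, and the list's largest changes at 6 h were in Bbc3, Eda2r, a death-domain receptor, Pmaip1 and Tnfrsf10b, another death receptor. Mitotic genes were lower at both times. Hedgehog and hair matrix genes were lower at 24 h but not at 6 h. Keratin-associated genes were higher at both times.

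The p53 target median was 0.96 at 6 h and 0.51 at 24 h, with Bbc3 at 4.27, 25 and 9.78 FPKM and Mgmt at 3.67, 8.71 and 29.3. The mitotic median was -0.65 and -0.94, with Mki67 at 12.9, 6.89 and 4.03 FPKM. The Hedgehog median was 0.07 and -0.87, and Shh stood at 5.21, 5.59 and 1.33 FPKM. The keratin-associated median was 0.48 and 0.89, with all 42 members higher at 24 h. Interferon genes had a median of -0.78 at 6 h and -0.19 at 24 h. Pdk4 (3.59) and Trim63 (3.17) were again among the largest at 6 h, and Lcn2 (3.52) at 24 h, while Saa3, at 36.9 FPKM at 24 h, lay far below its wild-type level. Counts were 243 higher and 167 lower genes at 6 h and 247 and 173 at 24 h, and rescaling moved the higher share at 24 h from 58.8% to 71.2%.

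Wild type and Krt17 knockout, each against its own controls, shared 65 higher genes at 6 h where independent lists would share 4.27, and 64 lower genes where they would share 5.36. At 24 h the shared numbers were 89 against 5.28 and 89 against 5.98. Across genes, which are not independent replicates, the log2 ratios correlated with r = 0.415 and 0.484. The difference between the responses, an interaction, was at least 2-fold for 628 genes at 6 h and 503 at 24 h, with smaller increases in the knockout at 24 h of Saa3 (-4.35) and of the neutrophil attractant Cxcl5 (-3.43). The p53 target list differed by 0.31 at 6 h against a difference of 0.11 in the median of all genes, and the mitotic list by 0.38. Before irradiation the median FPKM of the p53 targets was 10.0 in the Krt17 knockout and 12.5 in wild type, while their sums were 3086 and 2905. The mitotic medians were 11.4 and 12.4 FPKM. Rescaling moved the higher share of these genes at 6 h from 59.9% to 49.2%.

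The p53 knockout addressed which of these changes occurred without p53. The p53 target list stayed near its control level, and mitotic, Hedgehog and hair matrix genes were not lowered at 24 h. Keratin-associated genes were lower rather than higher. The neutrophil list, in contrast, stood higher at 6 h than in either other genotype, as did the single genes Saa3 and Lcn2.

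The p53 target median was -0.04 at 6 h and 0.04 at 24 h, with 0 of 38 members at least 2-fold higher at either time. Bbc3 stood at 4.02, 6.10 and 5.47 FPKM, Ccng1 at 20, 19.3 and 18.6, and Mgmt at 2.83, 2.28 and 3.82. Some list members were higher all the same, as were Fas at 0.94 and Btg2, an antiproliferative gene, at 0.95 at 6 h. The mitotic median was -0.20 and 0.22, with Mki67 at 22.2, 19.8 and 19.1 FPKM, and Shh stood at 7.14, 11.6 and 9.06. The interferon list had a median FPKM of 5.30, 6.39 and 3.23 at 0, 6 and 24 h, against 4.51, 0.887 and 2.62 in wild type. Its summed FPKM was 949, 700 and 495, against 428, 146 and 434 in wild type. The keratin-associated median was -0.65 at 6 h and -0.23 at 24 h, and the share of all genes with a Krtap symbol in the total was 8.57% and 10.7% against 13.0% in p53 knockout controls.

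Saa3 went from 10.1 to 1888 FPKM at 6 h in the p53 knockout and Lcn2 from 9.19 to 287. S100a9, a neutrophil and stressed-keratinocyte protein, had a log2 ratio of 2.77, Krt16, a stress keratin, of 2.03, and the neutrophil list (16 genes) had a median of 1.39, against 0.16 in wild type and 0.04 in the Krt17 knockout. By 24 h Saa3 was at 138 FPKM, the stress keratinocyte list had a median of -1.23, and Defb3, an antimicrobial peptide, stood at a log2 ratio of -2.93. The stress list was, however, 0.56 higher in p53 knockout than in wild-type controls. Pdk4 (3.72) and Trim63 (3.38) were higher at 6 h, as in the other genotypes. Counts were 318 higher and 155 lower genes at 6 h and 137 and 163 at 24 h.

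Compared with wild type, the response differed at least 2-fold for 844 genes at 6 h and 1138 at 24 h, led among described genes by Saa3 (8.10) and Saa1 (5.50), another acute-phase gene, at 6 h. The mitotic list differed by 0.74 and 1.38, the p53 targets by -0.51 and -0.34, the Hedgehog list by 0.99 at 24 h and the keratin-associated list by -1.21 at 24 h. The median of all genes differed by 0.18 and 0.25, and rescaling moved the higher share from 70.4% to 52.6% at 6 h and from 63.6% to 35.1% at 24 h. At 6 h the 2 genotypes shared 73 higher genes against 5.60 for independent lists and 28 lower genes against 4.94, with r = 0.296 across genes. At 24 h they shared 47 against 2.92 and 24 against 5.64, with r = 0.132. Different times also shared more than independent lists, as wild type at 24 h and the p53 knockout at 6 h had 80 higher genes in common against 6.75 at r = 0.0960, so such an excess does not by itself make 2 responses alike.

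**Figure D2:**
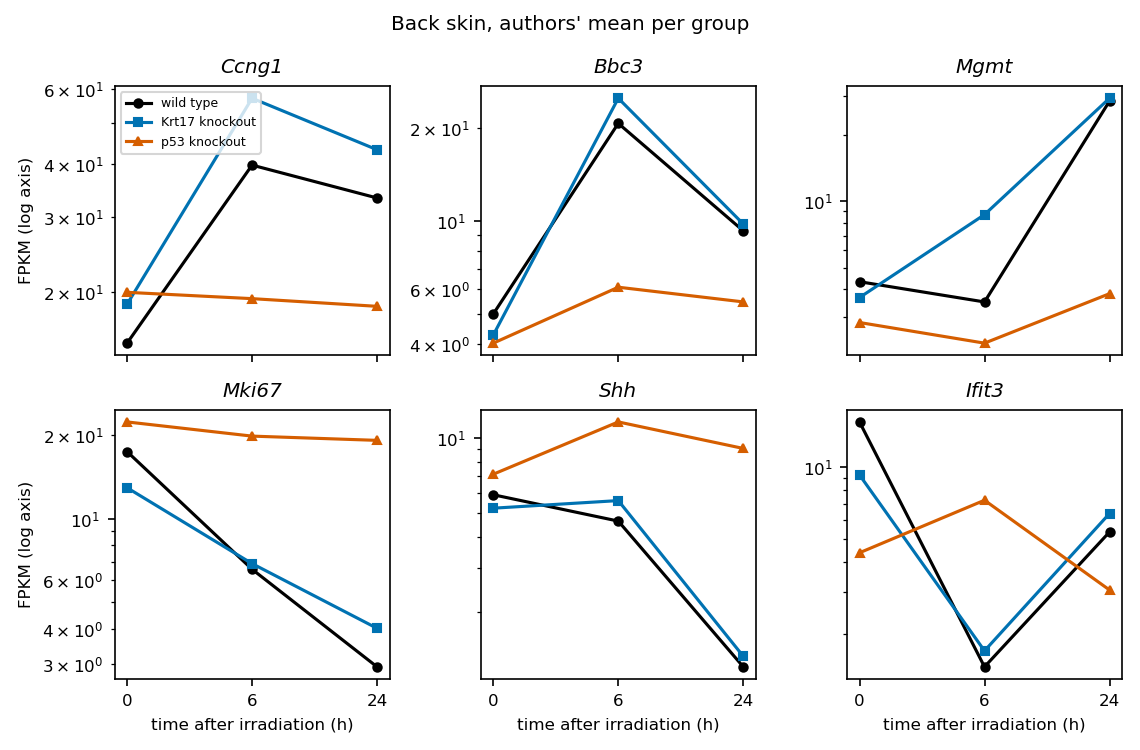
Mean FPKM per group (log axis) of Ccng1, Bbc3, Mgmt, Mki67, Shh and Ifit3 in back skin at 0, 6 and 24 h, with 1 line per genotype and no error bars because only means were given. Bbc3 reached 20.7 FPKM in wild type and 25 in the Krt17 knockout at 6 h but 6.10 in the p53 knockout.

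Before irradiation the genotypes already differed, which sets a scale for the other single ratios, though not for the noisier interactions. Wfdc18, a secreted protease-inhibitor-like gene, was higher in both knockouts (320.2 and 301 FPKM) than in wild type (28.2), and Fosb, an immediate early gene, was lower in both (log2 ratios -2.86 and -2.47). Krt17 led the lower genes of the Krt17 knockout at -6.37. Haemoglobin genes were higher in the p53 knockout, with Hbb-bs at 2.34, and fibroblast and matrix genes were lower in both knockouts, at -0.41 and -0.53. Both comparisons use the same wild-type control column, so a change shared by the 2 knockouts, as for Wfdc18, Fosb and the fibroblast list, does not count as 2 separate observations. The Krt17 knockout had 140 higher and 103 lower genes and the p53 knockout 170 and 96. Of 39 lists, 19 and 23 had medians outside the central range of matched random lists in these 2 comparisons, where chance gives 1.95, so lying outside that range does not by itself set a radiation effect apart.

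In wild-type footpad the question was what 40 Gy changed over time in skin with few hairs. The keratins of wounded or stressed epidermis, Krt6b and Krt16, were higher at each time and highest at T9. The calcium-binding alarm proteins S100a8 and S100a9 and the antimicrobial peptide Defb4 also peaked at T9. Most genes of the hair shaft and of its inner sheath were lower at each time. The p53 targets were higher throughout, and mitotic genes were lowest at T3.

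Krt6b stood at 17.7, 369, 589 and 4693 FPKM at T0, T3, T6 and T9, and Krt16 at 57.5, 407, 677 and 4938. S100a8 stood at 6.56, 150.1, 30.8 and 2354 FPKM. The stress keratinocyte list (35 genes) had medians of 0.63, 0.56 and 2.48, and the inflammatory list of 0.19, 0.36 and 1.28, with the alarm cytokine Il33 at 2.14 FPKM at T0 and 26.5 at T9. The p53 target list (39 genes) had medians of 0.90, 0.92 and 0.94, led by Ddit4l, an inhibitor of growth signalling, at log2 ratios of 3.23, 3.14 and 3.17 and by Ccng1 at 2.48, 2.11 and 2.05. The mitotic list had medians of -1.09, -0.47 and 0.00.

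Krt71, a keratin of the inner root sheath, stood at 17.6, 1.39, 2.24 and 0.227 FPKM in wild-type footpad. The inner root sheath list (16 genes) had medians of -0.64, -0.84 and -1.01, with 11, 13 and 12 members lower, but its summed FPKM did not fall at each time (483, 671, 456 and 546). The keratin-associated list (37 genes) had medians of -1.63, -1.76 and -2.04, but all genes with a Krtap symbol held only 0.0233% of the FPKM total at T0. Sebaceous gland genes were lower as well (-0.41, -0.92 and -0.83), with Scd3, a fatty acid desaturase, at -2.96 at T6. Interferon genes were higher at T6 and T9 (0.85 and 0.98), as was C1qa, a complement gene of macrophages (1.49 and 1.31). Fibroblast and matrix genes were higher at T6 in particular (0.93), with Col1a1 at 1.39. From T0 to T6, summed FPKM also rose for skeletal muscle (296 to 665) and mast cell genes (20.8 to 54.1). Endothelial (126 to 200) and nerve genes (120 to 184) rose too, while adipocyte genes fell (744 to 624). Defb8, an antimicrobial peptide, was 289.7 FPKM at T0, 5.92 at T3 and 0.919 at T6, and was listed at 0 at T9 and in the knockout at T6, which was treated as missing. Ece1 met the size rule but moved irregularly from column to column, and Slc15a4 met it through a single column, as it stood at 130.5 FPKM at T0 and between 7.98 and 11 in every other footpad group. Counts of higher and lower genes were 211 and 223 at T3, 342 and 184 at T6, and 433 and 225 at T9.

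The Krt17 knockout footpad showed the response without this keratin. Krt6b, Krt16, S100a8 and Defb4 were higher at each time, as in wild type, but stood highest at T6, and lower at T9. Slpi, a protease inhibitor, and Epgn, a growth factor for epidermal cells, followed the same course. Most hair sheath genes were lower at each time. Mitotic genes ended above their T0 level.

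Krt6b stood at 20.1, 231, 4738 and 1191 FPKM, Krt16 at 49.5, 199.97, 4574 and 1577, and S100a8 at 22.1, 152, 2476 and 202. The stress keratinocyte medians were 0.40, 2.1 and 1.5, and Il33 stood at 41.7 FPKM at T6 and 10.4 at T9 against 1.49 at T0. Epgn stood at 1.89, 13.6, 161 and 16.3. The p53 target medians were 1.28, 1.31 and 0.94, with Ccng1 at log2 ratios of 2.57, 2.68 and 2.25. The mitotic medians were -0.48, -0.15 and 0.83, and Ube2c, a mitotic enzyme, stood at 1.45 at T9. Krt71 stood at 19.2, 3.27, 1.63 and 0.446 FPKM, the inner root sheath medians were -0.58, -1.20 and -0.83 while the summed FPKM of that list stayed level (511, 517, 549 and 503), and the sebaceous list was lowest at T6 (-1.19), with Elovl3, a fatty acid elongase, at -3.49. Skeletal muscle genes were higher at T3 and T6 (1.32 and 1.01), and had been 0.85 higher than in wild type at T0. Counts were 273 higher and 157 lower genes at T3, 549 and 307 at T6, and 310 and 243 at T9, where rescaling turned the excess round to 264 higher and 270.0 lower.

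**Figure D3:**
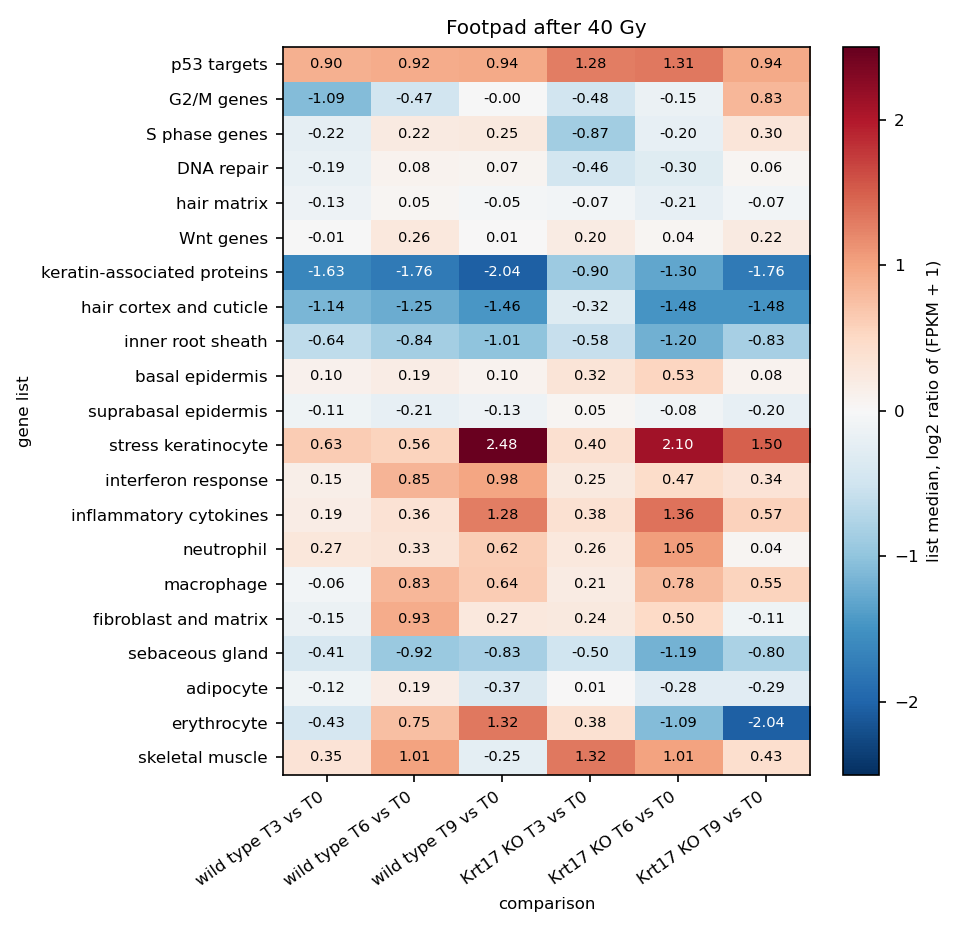
Median log2 ratio of FPKM + 1 over each gene list in irradiated footpad against T0 of the same genotype, with 1 mean column per group. The stress keratinocyte median was highest at T9 in wild type (2.48) and at T6 in the Krt17 knockout (2.1).

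**Figure D4:**
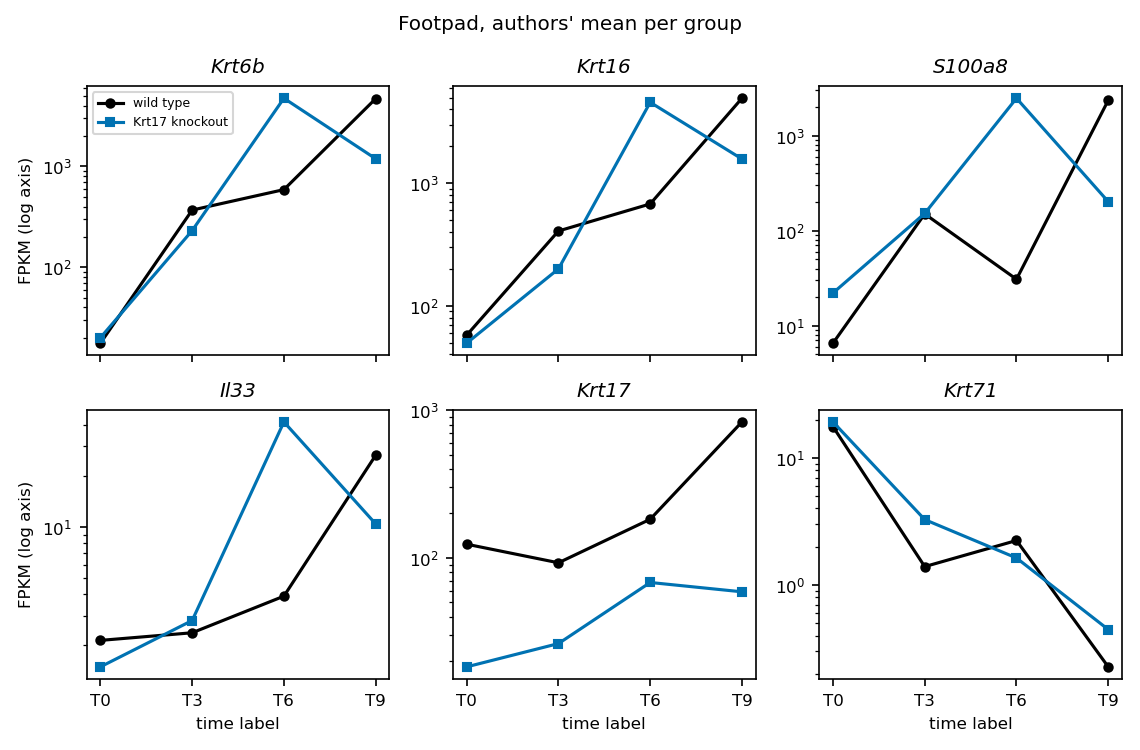
Mean FPKM per group (log axis) of Krt6b, Krt16, S100a8, Il33, Krt17 and Krt71 in footpad at T0, T3, T6 and T9, with 1 line per genotype and no error bars because only means were given. Krt6b stood at 4738 FPKM in the Krt17 knockout at T6 and at 589 in wild type.

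Before irradiation, Krt17 was among the lowest genes of the knockout footpad against wild type (-2.70). Sprr2b, a cornified envelope gene, was higher (340.2 against 35 FPKM), as was the acute-phase gene Saa1 (2.99), and the haemoglobin list stood at 1.20. In all, 126 genes were higher and 70 lower, and 16 of 38 lists lay outside their random range, where chance gives 1.9.

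The stress list and several inflammation genes differed between the 2 footpad responses in opposite directions at T6 and T9. At T6, Slpi (5.90), Saa3 (5.69), Defb4 (4.77) and S100a8 (4.67) were further above their T0 level in the knockout. At T9, S100a8 (-5.15) and S100a9 (-4.44) were less so, while Chil4, a chitinase-like protein of type 2 inflammation (40.9 FPKM in the knockout, 0.656 in wild type), and Sprr2a3, a cornified envelope gene (2.94), were more so, although both of these stood at least 8-fold above every other footpad column in that 1 column. The stress list differed by -0.27 at T3, 1.45 at T6 and -0.84 at T9, against 0.22 between the genotypes at T0. The p53 target list differed by 0.21, 0.24 and 0.07, and the mitotic list by 0.73, 0.32 and 0.85. The numbers of genes with a difference of 2-fold or more were 419, 486 and 474, and 196 between the genotypes at T0. The first 3 counts come from differences of 2 log2 ratios and the last from a single ratio. Noise alone would therefore let more genes pass in the interactions, and the larger counts do not show a genotype effect on the response.

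Wild type and Krt17 knockout footpad, each against its own T0, shared 91 higher genes at T3 against 4.18 for independent lists, 167 at T6 against 13.6, and 149 at T9 against 9.71, and 55, 121 and 118 lower genes against 2.54, 4.08 and 3.95. The knockout at T6 and wild type at T9 shared 266 higher genes against 17.2 and 127 lower genes against 5.01. For higher genes that was 15.5 times the independent number, against 12.3 times with wild type at T6, but for lower genes it was 25.3 times against 29.7 times. Such a ratio for higher genes was not particular to this pair. It was 15.3 for the knockout and wild type at T9, and 17.6 for the knockout at T9 with wild type at T3. Across genes, which are not independent replicates, log2 ratios of the knockout at T6 correlated with those of wild type at T9 with r = 0.675, and with those of wild type at T6 with r = 0.568, while the rank correlations were nearer, at 0.606 and 0.58. With a pseudocount of 0.1 FPKM in place of 1, each count of genes in all 23 comparisons was over 1.5 times larger.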

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

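Except for the test without the activation lists, the rescaling test and the tests of small RNA genes and shared exons, the tests in this part were chosen only after the result was seen.

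Haemoglobin and mast cell genes moved in opposite directions in different genotypes. In the footpad, the erythrocyte list (5 genes) had a median log2 ratio of -1.09 at T6 and -2.04 at T9 in the Krt17 knockout, against 0.75 and 1.32 in wild type, from a knockout T0 level 1.20 above wild type. In back skin, the mast cell list (8 genes) had a median of 0.78 at 6 h in the p53 knockout and of -0.60 in wild type. None of these differences was tested, since each group has only its mean, and no explanation was tested.

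The Krt17 knockout footpad at T6 resembled wild type at T9 more than at T6 in its higher genes, though not in its lower genes relative to independent lists, and only slightly by rank correlation (0.606 against 0.58), with Krt6b at 4738 FPKM in the knockout at T6 and at 4693 in wild type at T9. An exchange of these 2 columns is argued against by Krt17 itself, at 68.1 FPKM in the knockout at T6 and 92.6 in the lowest wild-type column. Wild type at T9, the other column of such an exchange, held the most Krt17 of all footpad groups. Without the stress keratinocyte, neutrophil and inflammatory lists, the correlation across genes was 0.637 with wild type at T9 and 0.559 at T6, and the rank correlation 0.602 and 0.579. The resemblance was thus not carried by the members of these lists alone. Leaving them out took the genes compared only from 13774 to 13709, so other activation genes stayed in. This test cannot exclude that stress and inflammation genes carried the resemblance. An earlier wave of epidermal activation without Krt17 may be part of the pattern, but no such shift was seen in the knockout at T3. Its correlation was 0.407 with wild type at T6 and 0.408 with wild type at T3. A stronger reaction of only 1 of the 2 averaged samples may also be part of the pattern. The means keep that open, since the stress list difference of 1.45 at T6 cannot be split by sample.

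In back skin at 24 h mitotic and hair matrix genes were lower and keratin-associated genes higher in wild type and the Krt17 knockout. The larger share of the FPKM total held by hair shaft transcripts cannot be the whole cause, because after rescaling the mitotic median in wild type was still -0.96. Less follicle tissue in the irradiated pieces, as the whole cause of the lower mitotic genes, was tested with the inner root sheath list (18 genes), which is no part of the pattern. In the Krt17 knockout an even loss of all follicle parts is argued against by the sheath median of -0.094. The sheath members ran from -0.45 to 0.57 and all lay above the mitotic median of -0.94. In wild type 17 of the 18 members lay above the mitotic median of -1.15, with a median of 0.025 and a range of -1.29 to 0.93. The gap between the sheath and mitotic medians (1.17) was smaller than that from the lowest sheath member to its median (1.31). The sheath list thus missed the criterion that it met in the Krt17 knockout. All 42 keratin-associated genes, which are follicle genes too, were higher in wild type (median 1.07). Less follicle tissue alone would not give that rise, but it is part of the pattern and no separate test. A smaller loss of follicle tissue beside another cause stays open in both. So does a loss of the hair matrix alone, since sheath and hair shaft genes do not measure that part of the follicle. A response that needs p53 could explain it, as the mitotic median was 0.22 in the p53 knockout against -1.15 in wild type. Differences between the sampled animals other than genotype stay open with 2 samples per group.

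Of the genes above 5 FPKM, 70 stood at least 8-fold from all other columns of their tissue in 1 column, 67 of them higher, a definition chosen after the data were seen. Small RNA genes made up 45.7% of them and 0.498% of the 11046 genes with 5 FPKM or more. Short transcripts, whose FPKM divides few reads by a small length, are a candidate explanation beyond gene type, as the 38 that are not small RNA genes had a median exon length of 195 bases against 969 in sets matched on gene type and highest FPKM (663 to 1674). Small RNA genes lying inside them were no more common than in sets matched on span (1.43%, with 4.29% in the median set and 0% to 10.0% in all but the extremes), a value below the matched median but within the matched spread, so this cause cannot be told apart from none. The same holds for exons shared with another gene (27.1% against 25.7%, with 17.1% to 35.7%). No biological explanation was tested.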

How the results depend on the processing

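The filter of 5 FPKM, keeping listed zeros and leaving out genes that stand apart in 1 column were chosen after seeing the data. Leaving out a replicate, a replicate block, a fit on the contrasted groups only and a camera test with estimated correlation were not run, since the tables hold only means. No paired analysis was possible because the samples of a group share replicate numbers with other groups in the labels but only the mean of each group was given. For the same reason the number of reads behind a value, and what it limits, is not known.

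The 308 results for genes named by the size of their change kept their sign under each alternative that could be computed for them. That was all 6 for 286 and all but the removal of single-column genes for 22. Krt17, Trp53 and list members were included only where they met the size rule. As these were the largest changes, and most alternatives leave the ratio of a gene as it was, a change of sign was hardly possible. Under a pseudocount of 0.1 FPKM, 120 of the 308 moved. Counts of genes changed at least 2-fold stayed within 1.5 times under no filter, rescaling, listed zeros kept and removal of single-column genes in all 23 comparisons. For no filter this was fixed in advance except in the interactions, since a gene below 1 FPKM in each column cannot reach 2-fold. The listed zeros and the single-column genes were too few to move a count that far. Of 507 list results in back skin 258 lay outside their random range, and 250 to 260 under the alternatives, and of 380 in the footpad 232 did, and 202 to 239. The count of 250 was out of 494 and that of 202 out of 350, as the filter of 5 FPKM left fewer lists with 5 members.

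A pseudocount of 0.1 FPKM raised every count, by construction, since it gives more weight to genes with low values. In the footpad the counts became 952, 1199 and 1303 in wild type at T3, T6 and T9, 911, 1527 and 1133 in the Krt17 knockout, 545 between genotypes at T0, and 1084, 1113 and 1102 for the interactions. In back skin they became 1794 and 1791 in wild type at 6 h and 24 h, 1832 between these times, 1063 and 1026 in the Krt17 knockout, 1008 and 718 in the p53 knockout, 653 and 638 for the knockouts at 0 h, 1601 and 1308 for the Krt17 interactions and 1880 and 2299 for the p53 interactions.

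A filter of 5 FPKM lowered 16 counts by over 1.5 times, since fewer genes were compared. In the footpad they became 280, 343 and 416 in wild type, 275, 564 and 323 in the Krt17 knockout, 108 between genotypes at T0 and 218, 272 and 251 for the interactions. In back skin they became 268 and 274 in the Krt17 knockout, 190 in the p53 knockout at 24 h, 357 and 255 for the Krt17 interactions and 517 for the p53 interaction at 6 h.

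Of the list medians outside their random range in the main calculation, 14 reversed their sign, 4 of them under 2 alternatives. Most of the 14 were close to 0, and the cause was not tested. Changes of sign among medians inside their range were not counted. Without the filter, in the footpad interaction at T6, dermal papilla went from 0.39 to -0.028 and T and NK cells from 0.36 to -0.014, and in wild-type back skin apoptosis at 6 h went from 0.04 to -0.034 and matrix remodelling at 24 h from 0.06 to -0.001. After rescaling, in wild-type back skin apoptosis at 24 h went from -0.01 to 0.16 and the keratin-associated list at 6 h from -0.14 to 0.035. In the p53 interactions at 6 h and 24 h, rescaling took apoptosis from 0.03 and 0.02 to -0.16 and -0.24, endothelial genes from 0.03 and 0.02 to -0.13 and -0.23, and at 24 h interferon genes from 0.09 to -0.086. With a filter of 5 FPKM, in wild-type back skin apoptosis at 24 h became 0.14, matrix remodelling at 24 h -0.078, and senescence at 6 h and 24 h went from 0.12 and 0.15 to -0.34 and -0.14. With the same filter apoptosis in the p53 interaction at 6 h became -0.21, endothelial genes in that at 24 h -0.024, and dermal papilla in the Krt17 knockout at 24 h went from 0.08 to -0.012.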

Other observations

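The time-of-day test in this part was chosen only after the result was seen, and the glucocorticoid list was written after Pdk4, Zbtb16, Txnip, Fkbp5 and Tsc22d3 had been noticed, but before its own values were seen.

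At 6 h in back skin, Pdk4, Zbtb16, Txnip, Fkbp5 and Tsc22d3, genes that glucocorticoids or fasting raise, were higher in all 3 genotypes, p53 knockout included. Of these, Fkbp5 and Tsc22d3 lay outside the naming rule and were chosen after their values were seen. Fkbp5, a chaperone of the glucocorticoid receptor, went from 6.68 to 33.0 FPKM in wild type, from 7.38 to 36.0 in the Krt17 knockout and from 8.76 to 40.7 in the p53 knockout. The 13 other measured glucocorticoid targets had medians of 0.99, 0.79 and 1.03 in these genotypes at 6 h, above their random ranges, and of 0.13, 0.16 and 0.21 at 24 h, smaller but still above their random ranges. A glucocorticoid or fasting response after irradiation or handling may therefore account for these genes, and the lowest of the medians at 6 h, 0.79, would have spoken against it had it lain inside its range. Another time of day than in the controls could act the same way. Dbp, an output gene of the clock, had log2 ratios of -1.28, -1.25 and -1.65 at 6 h in wild type, Krt17 knockout and p53 knockout, but at 24 h stood at -1.15 in wild type, -0.16 in the Krt17 knockout and -0.67 in the p53 knockout, which leaves this open. The labels give no clock time and no unirradiated skin at 6 h.

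Genes of the unfolded protein response were higher at 24 h in back skin of each genotype, with list medians of 0.52, 0.34 and 0.34 over 17 genes, after -0.18, -0.08 and -0.11 at 6 h. Atf3, a stress transcription factor, stood at 1.87 in wild type and 1.75 in the p53 knockout at 24 h.

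Genes of Langerhans and dendritic cells were lower at 24 h in back skin of each genotype (-0.60, -0.56 and -0.33). Mgl2, a lectin of dermal dendritic cells, stood at -1.08 in wild type and -1.70 in the Krt17 knockout, and H2-Aa, which presents antigen, stood at -0.98, -1.05 and -0.90.

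In the footpad, melanocyte genes were higher at each time in both genotypes, with list medians of 0.31, 0.81 and 0.54 in wild type and 0.54, 0.44 and 0.64 in the Krt17 knockout. Mlana, a pigment cell antigen, led the list in wild type at T6 (2.0).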
